A study of Mus musculus with 2 samples.

How the data were processed

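RNA from gastrocnemius muscle, the large calf muscle, of male mice of the B6XSJL background aged 12 months was profiled on 2 single-channel expression arrays. One array held control muscle and the other held muscle collected 4 h after a 15 min period of isometric contractions, in which the muscle develops force without shortening. The labels do not say whether the 2 muscles came from 1 mouse or from 2, nor whether RNA was pooled.

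The deposited table holds 149 features per array as whole-number intensities on a linear scale, 0 or between 7376 and 49869. The array platform, the image analysis, the background correction, the listing threshold and the scaling between arrays are not given in the sources used here. The unit was taken from the values themselves. No intensity lay between 0 and the dimmest listed value, which was 15.0% of the brightest value on the control array and 14.8% on the 4 h array. A value of 0 was therefore read only as listed at 0, and no fold was computed against it except in the pseudocount setting described below. The quantile normalization described below also took zeros as values.

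The features carry identifiers made of a letter and a number (58 beginning with M, 91 with T), which the table does not pair with genes. None matched a gene identifier, locus tag, Ensembl identifier or RefSeq accession in the GRCm38.p6 gene table. 1 gene symbol and the synonyms of 6 genes happen to be spelled like a feature identifier and were not used. The gene lists, the rule for named items and the settings compared were fixed before the data were examined. The 10 gene lists (among them heat shock proteins, antioxidant enzymes, cytokines, apoptosis genes, muscle genes, markers of other cell types and housekeeping genes) could therefore not be applied. Their medians and their comparison with random lists were not computed.

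The log2 ratio of the 4 h intensity over the control intensity was computed for each feature above 0 on both arrays, without further scaling, and features at least 2-fold apart were counted. With 1 array per group no spread between animals or arrays can be estimated, so no test was made and no p-value or error is attached to any value. The number of arrays limits the precision of every ratio. The rule for named items took the 12 highest and 12 lowest ratios, up to 4 members per gene list and the housekeeping genes. Because the identifiers have no gene names, only the first 2 in each direction are named. The other settings were median centring, quantile normalization over all 149 features, a pseudocount of 7376, omission of the dimmest 25% of features, and thresholds of 1.5-fold and 3-fold. Centring on housekeeping genes could not be carried out without names. The calculation was tested on simulated ratios for the 28 measured features and recovered the 3 features made higher and the 4 made lower. The simulated ratios carried no noise and no values of 0, so this checks the arithmetic only. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.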

Results

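The series set control mouse gastrocnemius muscle beside muscle taken 4 h after a bout of isometric contractions, with 1 array of 149 features in each group. On the control array 46 features (30.9%) were above 0, with a median of 15462 intensity units and a maximum of 49152. On the 4 h array 30 features (20.1%) were above 0, with a median of 12526 and a maximum of 49869. The listed intensities summed to 919530 in control muscle and 580796 after contractions, a ratio of 0.632. Both sums include 4 features at the top of the intensity range, where the arrays could not be compared. There were no replicate arrays, so none of the differences below could be compared with a spread between replicates.

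The first comparison asks which features were measurable in each muscle. Of the 149 features, 28 were above 0 on both arrays, 18 on the control array alone, 2 on the 4 h array alone, and 101 on neither. The 18 features listed at 0 only after contractions were dim in control muscle, at 7408 to 15318 units with a median of 11421. The 2 features listed at 0 only in control muscle had 4 h intensities of 7415 and 8191. All 23 features above the control median of 15462 units were also above 0 after contractions, whereas 5 of the 23 listed at or under that median were.

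The second comparison asks how the measured features differed in size after contractions. Of the 28 features above 0 on both arrays, 21 were dimmer and 7 brighter 4 h after contractions, and the median log2 ratio was -0.52, a ratio of 0.697. The median and the counts below leave out the 18 features listed on the control array alone and the 2 listed on the 4 h array alone. No intensity under 7376 units is listed, so a feature dim in control muscle could not show a strongly lower ratio. Of the 7 brighter features, 4 lay at the top of the intensity range on both arrays, where no direction can be read. After quantile normalization 14 of the 28 features were dimmer, 13 brighter and 1 equal, and 17 kept the direction they had as deposited. At a 2-fold difference, 1 feature was higher and 6 were lower. A further 6 features were between 1.5-fold and 2-fold lower, and 15 were less than 1.5-fold apart. After median centring, which subtracts the median of -0.52 from every log2 ratio, 1 feature was at least 2-fold higher and 0 were 2-fold lower. After quantile normalization the counts were 4 higher and 0 lower, and only 1 of the 4 was 2-fold higher as deposited. With 46 values above 0 on the control array and 30 on the 4 h array, the dimmest listed control values were averaged with zeros. This lowered them and raised their ratios, so the 4 are not evidence of increases. Median centring balances the directions among the 28 features by construction. Quantile normalization brought both arrays to a common distribution over all features, zeros included. That takes out a general difference in level between the arrays, but it does not fix the directions among the 28.

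Feature T9 had the highest ratio, with an intensity of 7376 in control muscle and 19039 after contractions, 2.58-fold higher (log2 ratio 1.37, or 1.89 after median centring). Its control intensity was the dimmest listed value on either array. With the pseudocount, which shrinks the ratios of measured features, its log2 ratio was 0.84, under 2-fold. Leaving out the dimmest 25% of features, by mean log2 signal over both arrays, removed T9 itself. That no feature was then 2-fold higher follows from the filter and is no check on T9. Feature M906 was next, at 34520 units in control muscle and 47369 after contractions, 1.37-fold higher (log2 ratio 0.46, or 0.98 after median centring). Its 4 h intensity lay close to the brightest value on that array, 49869. The lowest ratios were those of T32, at 17530 units in control muscle and 7722 after contractions (log2 ratio -1.18), and T34, at 18992 and 8523 units (log2 ratio -1.16). After median centring these log2 ratios were -0.66 for T32 and -0.64 for T34. The genes behind these 4 features were not identified here, so their genomic positions are not given.

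At the top of the range the arrays could not be compared. On the control array 4 features shared the identical maximum of 49152 units, treated here as a ceiling, and on the 4 h array the same 4 features lay between 49747 and 49869, with log2 ratios of 0.017 to 0.021. A ratio between values at a ceiling cannot show a difference in either direction. The next brightest control feature, at 48968 units, had 38815 units after contractions (log2 ratio -0.34). Among the 24 measured features other than these 4, 21 were dimmer and 3 brighter after contractions as deposited, with a median log2 ratio of -0.61 and quartiles of -0.94 and -0.35. These values leave out the 18 features listed on the control array alone. Over the 19 features above the control median, none of which was at 0 after contractions, the median log2 ratio was -0.84. Across these 24 features, which are not independent replicates, the log2 intensities on the 2 arrays had a Pearson correlation of 0.659 and the intensities a Spearman correlation of 0.643.

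**Figure D1:**
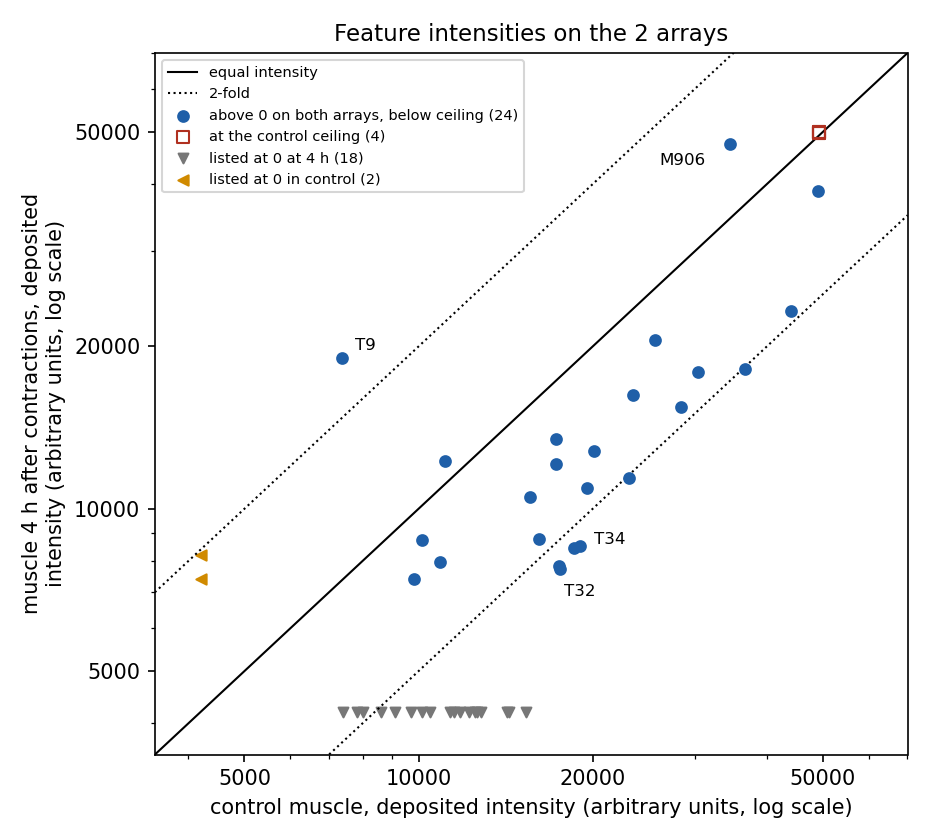
Each point is a feature, with its deposited intensity in control muscle on the x axis and 4 h after contractions on the y axis (arbitrary units, both axes logarithmic, 1 array per group). The solid line marks equal intensity and the dotted lines a 2-fold difference; triangles at the edges are features listed at 0 on 1 array, drawn at an arbitrary position on that axis. Most points lie under the line of equal intensity, 6 of them at least 2-fold lower, and T9 is the only circle above the upper 2-fold line. The 4 squares overlap.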

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

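Against 1 feature at least 2-fold higher and 6 at least 2-fold lower as deposited, median centring gave 1 and 0, and quantile normalization gave 4 and 0. The quantile targets include zeros, 103 on the control array and 119 on the 4 h array, so the dimmest listed control values were averaged with zeros and their ratios rose. A pseudocount of 7376, the dimmest listed value, puts every feature at 0 on 1 array at least 2-fold apart. The 2 higher and 18 lower it gave over all 149 features were these, none counted as deposited. Leaving out the dimmest 25% of features gave 0 higher and 4 lower, the 4 being among the 6. A 1.5-fold threshold gave 1 and 12, and a 3-fold threshold 0 and 0. The median log2 ratio of -0.52 became 0.0 with the pseudocount, where 101 features are 0 on both arrays, -0.57 without the dimmest 25%, and -0.61 without the 4 features at the control ceiling, an alternative chosen after seeing the data that left the counts at 1 and 6. The log2 ratio of T9 was 0.84 with the pseudocount and 2.74 after quantile normalization, which averaged its control value with a 0. There M906 (0.81), T32 (-0.51) and T34 (-0.37) kept direction too. Median centring and the pseudocount cannot reverse these 4. No signal under 7376 units is listed, so differences among dim features cannot be measured. Centring on housekeeping genes and the gene list medians were not run for lack of gene names. No paired analysis was possible because each group holds 1 sample.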

Other observations

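The tests of explanations in this part were chosen after the values were seen. As deposited, the median log2 ratio of features below the ceiling was -0.41 over 7 features beginning with M and -0.65 over 17 beginning with T. The ratios overlapped: those beginning with M ran from -0.92 to 0.46, within the range of -1.18 to 1.37 for T. What the letters stand for is not given in the sources used here. All 46 listed intensities on the control array were even numbers, whereas 22 of the 30 on the 4 h array were odd.

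The lower deposited intensities of most features after contractions have a technical candidate explanation, a single brightness factor left between the arrays. If the arrays had been brought to a common level through their brightest features, which sit at a ceiling, a weaker labelling or exposure of the 4 h array could remain in all other features. A single factor predicts nearly equal log2 ratios, and the median absolute deviation of the 24 ratios below the ceiling was 0.284. Without a repeat array this cannot be set against measurement noise, so a brightness factor and lower transcript levels after contractions cannot be told apart for these features.

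The 18 features listed only in control muscle may reflect a listing threshold, near the dimmest listed 4 h value of 7404 units, met by lower signals on the 4 h array. The 19 features above the control median and below the ceiling, all listed on both arrays, had a median log2 ratio of -0.84. At that ratio 15 of the 18 features would pass under 7404 units and 3 would not. Another 5 features at or under the control median would pass under it too, yet were listed after contractions, so this ratio misplaces 8 of the 23 dimmer control features. With no repeat array to give the scatter of single ratios, the explanation stays open, as does a change in these transcripts after contractions.

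Feature T9 had the highest ratio of the measured features. The tables argue against a single brightness factor between the arrays as its whole cause, because such a factor would raise the other features too: the 23 others below the ceiling had a median log2 ratio of -0.65, with quartiles of -0.97 and -0.38. Noise of a control value at the listing threshold stays open, since only 1 control array measured T9. An increase of this transcript after contractions is a hypothesis that these 2 arrays cannot test.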
